A study of Homo sapiens with 16 samples.

How the data were processed

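The series measured the response of human fibroblasts to serum starvation followed by refeeding on 2-colour spotted arrays. Per the labels, each of the 16 arrays set cells at 0 min against cells at 60 min of refeeding, with the 0 min material in channel 1 and the 60 min material in channel 2. The arrays were hybridised with 4 kinds of target, namely RNA and the RAP targets of primer19, primer22 and primer28, with 4 slides each. The labels do not say what RAP stands for, which fibroblast line was used, or whether RNA and RAP targets came from the same extracts, and none of this is assumed here. The labels describe slides 1 and 2 of a target as technical duplicates and slides 3 and 4 as biological duplicates.

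The deposited values are scores, 1 signed value per spot and array that compares the 2 channels. Background correction, within-array normalization and dyes are not given in the sources used here. On every slide the median absolute value of the deposited score was 0.437, and the medians lay between -0.028 and 0.031, so the deposited arrays had already been centred and brought to 1 scale. The most extreme values were -22.6 and 16.3. The log base and the scaling factor of the score stay unknown, so values are given in deposited units and no fold is computed. A log2 ratio had been assumed when the tests were designed, and the same limma test was kept for the score. The direction of the ratio is also unstated: the sign is kept as deposited, and a positive or negative value is not read as higher or lower at 60 min. No dye swap is recorded, so a dye effect of a single clone is part of its value.

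Each array holds 13872 spots. The spot numbers fall into 4624 clones with 3 spots each, since all 2318 annotated clones had 1 accession at their 3 positions. In the platform annotation 2247 clones have 1 gene symbol, 71 have several, and 2306 are unnamed here. The named clones stand for 2153 genes, and 0 symbols needed an update. Genes were named only from clones with 1 symbol. Signal over background is not known for any spot, so the number of slides and of spots with a value limits the precision: between 8499 and 13872 spots per slide had a value.

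Each array was centred on the median of its spots. The spots of a clone were averaged where at least 2 of the 3 had a value, a minimum chosen after the missing values had been seen and before any test was run. Slides 1 and 2 of a target were averaged as 1 sample, and slides 3 and 4 were taken as 1 sample each, which gives 3 samples per target. The labels leave open whether slides 3 and 4 are separate samples or duplicates of each other, so counts with both averaged as 1 sample stand beside the results. A clone was tested in a target with values from at least 2 of the 3 samples. One limma fit (version 3.58.1 in R 4.3.3) of all 4 targets gave each target's mean against 0 and each RAP target minus RNA, with an eBayes moderated test, up to 8 residual degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard errors (SE) come from the spread pooled over the targets, so a target that spreads more than the others gets a smaller SE than its own samples would give. IL11 had an SE of 0.34 in every target, while its SD between the 3 samples was 1.20 in RNA and 0.15 to 0.23 in the RAP targets. The p-values measure the spread between these samples, and the labels do not say whether these came from separate cultures.

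The fit was tested on simulated data with the real missing values and clone spreads and with 200 changed clones per target. Over 5 simulations of the 3982 clones tested in RNA, it recovered 36.8% of shifts of size 1, 76.7% of size 2 and 93.9% of size 4, and 4.97% of its calls were false. For RAP primer22 minus RNA, over 3520 clones, it recovered 31.2%, 66.7% and 89.3% of these sizes, with 4.08% of calls false. The simulated values were independent and normal, with 1 spread per clone for all targets and no offset of unchanged clones. Unequal spreads between targets and dye effects of clones were not simulated. The shares of false calls therefore do not cover these.

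Before the data were examined, the tests, 18 gene lists and the rule for named genes were fixed. The rule takes, per target, the 10 genes with the largest mean of each sign among clones past the threshold with 1 sign on every slide, up to 4 passing members of each list, and a panel of serum response genes whether or not they passed. For each RAP target minus RNA it takes the 5 largest passing differences of each sign. Of the panel (FOS, EGR1, JUN, JUNB, ATF3, MYC, IER3, DUSP1, ZFP36 and NR4A1), only IER3 was among the clones that could be named and tested. Lists were tested on 1 value per gene, the mean of its clones, with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run on the 946 genes complete in all samples. Overlaps were tested with one-sided Fisher's exact tests. Correlations are across clones, which are not independent replicates, and carry no p.

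The alternatives changed the centring, scaling, filters, averaging of spots and slides, the model, the threshold and the slides used. Those on the spots of a clone, on RAP primer19 slide 4 alone and on centring over the clones present on all 16 slides were chosen after seeing the data. A filter on dim spots was not run, as no intensities were used here.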

Results

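The data covered 16 arrays of human fibroblasts, each setting serum-starved cells at 0 min against cells refed for 60 min, with 4 slides for RNA and 4 for each of the RAP targets of primer19, primer22 and primer28. The title of the series sets RNA against RAP, so the comparisons asked which genes had values away from 0 in each target and whether the RAP targets gave the values that RNA gave. All values are in deposited units of unknown log base, with the sign as deposited. Between 10971 and 12017 of the 13872 spots had a value on the RNA slides, 9425 to 13872 on the primer19 slides, 9016 to 10575 on the primer22 slides and 8499 to 9506 on the primer28 slides. RAP primer19 slide 4 was the slide with a value at every spot, while the other primer19 slides lacked 29.5% to 32.1% of them.

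Slides resembled each other weakly. Across clones, Pearson's r between the technical duplicates was 0.227 in RNA, 0.229 in primer19, 0.176 in primer22 and 0.245 in primer28. Slides 3 and 4 correlated at 0.286 in RNA, 0.406 in primer19, 0.159 in primer22 and 0.051 in primer28. The median SD of a clone between technical duplicates was 0.27 in RNA and 0.22 to 0.23 in the RAP targets. Between the 3 samples it was 0.29 in RNA, 0.35 in primer19, 0.30 in primer22 and 0.37 in primer28. The technical SD rests on fewer values per clone than the SD over the 3 samples, which by itself lowers its median. The technical duplicates also enter the 3 samples as their mean. These medians therefore cannot show whether technical duplicates agreed better than samples did.

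**Figure D1:**
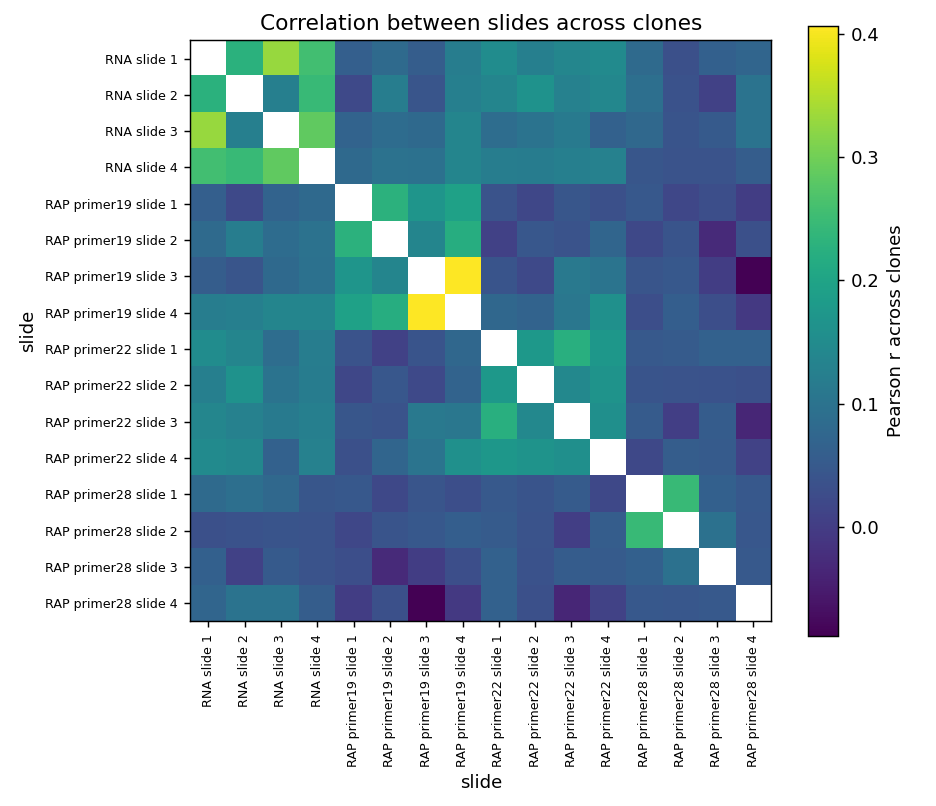
Pearson's r across clones for each pair of the 16 slides; both axes list the slides by target and the colour gives r, with the diagonal left white. The highest r, 0.406, joins RAP primer19 slides 3 and 4, and slides of primer28 reach at most 0.0997 with slides of RNA.

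In RNA, NR4A2, a nuclear receptor of the immediate early class, had a mean of 5.30 ± 0.33 (SE, n = 3 samples, limma adjusted p = 3.96e-05). ZC3H12A, a ribonuclease that degrades cytokine mRNAs, stood at 5.0 ± 0.27 (adjusted p = 1.80e-05), and RGS16, a regulator of G-protein signalling, at 4.19 ± 0.21 (adjusted p = 0.000684). The cytokine IL11 had 3.90 ± 0.34, the Krüppel-like factor KLF10 had 3.86 ± 0.26, the survival factor MCL1 had 3.25 ± 0.38 and the matricellular protein CCN2 had 3.15 ± 0.27. PRAME (3.16 ± 0.42) and the kinase STK38L (3.12 ± 0.26) also passed. ID4, an inhibitor of DNA binding, had 5.04 ± 0.97 on 1 clone (adjusted p = 0.0238) and -0.23 ± 0.71 on its other clone (adjusted p = 0.981), so its clones disagreed. In all, 106 of 3982 clones passed, 66 positive and 40 negative, of which 46 carried a gene name. With slides 3 and 4 averaged as 1 sample 20 passed, 18 positive and 2 negative. The balance of signs moved with other settings too, with 34 positive and 3 negative genes on 1 value per gene, 93 and 131 clones with all 3 spots needed, and 98 and 108 with all slides kept and a random block.

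Of the 7 measured immediate early transcription factors, 4 passed in RNA, all positive: NR4A2, KLF10, the AP-1 subunit JUND (1.62 ± 0.26) and the repressor SNAI2 (1.00 ± 0.16). The list's median was 1.71, and 6 members passed when adjusted over the list alone (camera adjusted p = 4.05e-22). With an estimated correlation the adjusted p = 0.00258 rests on the 3 members complete in all samples, NR4A2, JUND and SNAI2, all of which passed, and leaves out ELF3 (-1.10) among others. Of 5 early response and growth arrest genes, 3 passed positive, MCL1, CCN2 and the serum- and glucocorticoid-regulated kinase SGK1 (1.74 ± 0.26), and 4 when adjusted over the list alone (camera adjusted p = 4.14e-13). With an estimated correlation the adjusted p = 0.00258 rests on the 3 passing genes alone. IER3, which it leaves out, had -0.50 ± 0.60 (n = 2 samples, limma adjusted p = 0.896). Of 6 secreted factors 2 passed positive, IL11 and the chemokine CCL7 (2.03 ± 0.28), and 3 when adjusted over the list alone (camera adjusted p = 3.97e-07). With an estimated correlation the adjusted p = 0.0416 rests on 2 complete genes, IL11 and STC2 (0.22). INSIG1, a sterol-regulated protein of the endoplasmic reticulum, passed at 2.24 ± 0.36 as 1 of 3 genes of cholesterol and fatty acid synthesis (camera adjusted p = 0.0245, with fewer than 2 complete genes for an estimated correlation). ODC1, the enzyme that opens polyamine synthesis, passed at 1.54 ± 0.28 as 1 of 5 genes of ribosome biogenesis and translation. The tropomyosin gene TPM1 had 2.14 ± 0.26 on 1 clone (adjusted p = 0.00254) and -0.26 ± 0.24 on the other (adjusted p = 0.776).

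The named genes with negative calls of 1 sign on every slide numbered 7 in RNA. CIITA, the transactivator of MHC class II genes, had -2.18 ± 0.33 (limma adjusted p = 0.0125), the syntrophin SNTB1 had -1.91 ± 0.23 (n = 2 samples) and the chloride exchanger CLCN4 had -1.26 ± 0.26. SPDYE5 (-1.74 ± 0.27), CENATAC (-0.78 ± 0.17) and NIPAL4 (-0.62 ± 0.14) also passed, as did 1 clone of the splicing factor SRSF1 (-1.72 ± 0.38), whose other clone had 0.09 ± 0.26. The RNA count fell without any 1 of the 3 samples or without the pooled spread: 12 clones passed without slide 3 of every target, 16 without slide 4, 17 without slides 1 and 2 and 17 when RNA was fitted alone. It rose to 224 when all 3 spots of a clone were needed and to 257 over the 1433 clones with values on all 16 slides, where 210 of the calls were negative.

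**Figure D2:**
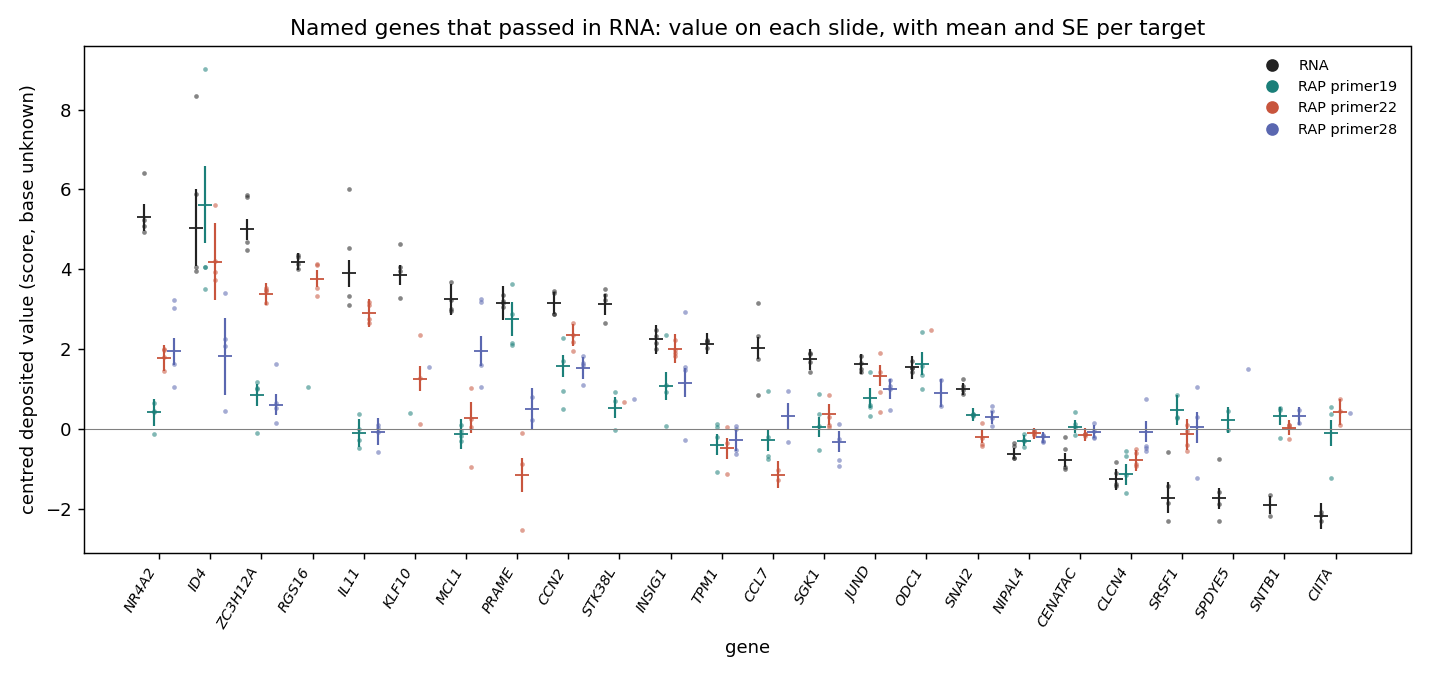
Centred deposited values (score, y axis) of the named genes that passed in RNA (x axis); points are slides, horizontal marks the mean of the 3 samples and bars the SE from the fit, by target. NR4A2 had a mean of 5.30 in RNA and 0.41 in primer19, and CCN2 had positive means in every target.

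With RAP primer19, 23 of 4038 clones passed, 13 positive and 10 negative. SST, the peptide hormone somatostatin, had 6.31 ± 0.95 (n = 3 samples, limma adjusted p = 0.0344), and ID4 had 5.62 ± 0.97 on 1 clone and 0.98 ± 0.58 on the other. UPP1, a uridine phosphorylase, had 3.57 ± 0.61, PRAME 2.75 ± 0.42, LRFN5 2.49 ± 0.38 and CCN2 1.57 ± 0.27. Negative values passed for GINM1 (-1.31 ± 0.16), the lipid phosphatase PLPP3 (-1.24 ± 0.17), the transcription factor MLX (-1.21 ± 0.20), IMPACT (-1.07 ± 0.19) and the GTPase ARF5 (-0.82 ± 0.15). CCN2 was the passing gene among 4 early response genes, and no list passed camera (lowest adjusted p = 0.620). By fry, on 3 complete genes each, the immediate early and early response lists had adjusted p of 0.0333 and 0.0278. Fry tests a list's own genes against 0, and camera tests them against the other genes. Of all measured members, 3 of 6 and 3 of 4 had a positive mean. In the 17 lists without a passing member, 15 of 80 genes had an unadjusted p under 0.05 in limma, against 233 of all 2003 genes. IER3 had 0.55 ± 0.60 (n = 2 samples, limma adjusted p = 0.860). Without primer19 slide 4, where SST stood at 10.3 against 3.82 to 4.49 on the other slides, 6 clones passed, 4 of them among the 23. Of the 11 named genes SST passed without it (4.29, adjusted p = 0.00293), and all 11 kept their sign. With limma 0 clones passed without slide 3, slide 4 or slides 1 and 2 of every target, with 285, 273 and 375 clones at an unadjusted p under 0.05. Quantile normalization and a fit of primer19 alone also gave 0, with 477 and 342 such clones, and averaging slides 3 and 4 as 1 sample gave 1 clone.

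With RAP primer22, 58 of 3638 clones passed, 43 positive and 15 negative. HS2ST1, a heparan sulfate sulfotransferase, had 4.47 ± 0.25 (n = 2 samples, limma adjusted p = 0.000351). RGS16 had 3.76 ± 0.21, the sorting nexin SNX10 3.69 ± 0.40 (n = 2 samples) and ZC3H12A 3.37 ± 0.27. The mitochondrial ribosomal protein MRPS12 (3.09 ± 0.43, n = 2 samples), the glucose transporter SLC2A3 (3.01 ± 0.41), IL11 (2.91 ± 0.34), CCN2 (2.35 ± 0.27) and sarcolipin, SLN (2.23 ± 0.24), passed too. Spots missing on the other primer22 slides had 3.02 to 3.49 times the median absolute value of spots present on them. Whether this adds to the size of genes with n = 2 samples was not tested. Of 7 immediate early transcription factors 2 passed, NR4A2 (1.78 ± 0.33) and JUND (1.34 ± 0.26), and 3 when adjusted over the list alone (camera adjusted p = 0.00631, but adjusted p = 0.324 with an estimated correlation). CCN2 passed among 4 early response genes, with 2 passing when adjusted over the list alone (camera adjusted p = 0.00486, but adjusted p = 0.324 with an estimated correlation). By fry, on 3 complete genes each, the immediate early and early response lists had adjusted p of 0.00518 and 0.000302. Fry also passed secreted factors (adjusted p = 0.00736, 2 complete genes) and actin cytoskeleton and heat shock genes (adjusted p = 0.0327 and 0.0327, 3 complete genes each). INSIG1 passed at 2.01 ± 0.36 as 1 of 2 genes of cholesterol and fatty acid synthesis (camera adjusted p = 0.00631), and the interferon-induced OAS2 at 2.56 ± 0.29 (n = 2 samples) as 1 of 4 interferon response genes (camera adjusted p = 0.19). IL11 was the 1 passing member of 5 secreted factors, whose median was -0.25 (camera adjusted p = 0.734). Adjusted over that list alone, 2 positive and 2 negative members passed. Among named genes that passed with 1 sign on every slide, the most negative were LETM1 (-2.10 ± 0.40), GABPB1 (-2.03 ± 0.26, n = 2 samples), the calcium channel CACNA1D (-1.89 ± 0.32, n = 2 samples) and FAM72B (-1.85 ± 0.26). TMEM253 (-1.66 ± 0.23), LTA4H (-1.55 ± 0.23), TRIM24 (-1.40 ± 0.19), RAC3 (-1.37 ± 0.26), C19orf53 (-1.13 ± 0.23) and the proteasome subunit PSMB3 (-0.98 ± 0.20) followed. Without slide 3 of every target 13 clones passed, without slide 4 only 1, without slides 1 and 2 18, and with slides 3 and 4 averaged as 1 sample 15, and 0 passed when primer22 was fitted alone with limma, where 467 had an unadjusted p under 0.05. In the 13 lists without a passing member, 8 of 59 genes had an unadjusted p under 0.05, against 272 of all 1885 genes.

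With RAP primer28, 13 of 3259 clones passed, 11 positive and 2 negative. LRRC4 had 2.63 ± 0.39 (n = 3 samples, limma adjusted p = 0.0200), the ribosomal protein RPL10A 1.98 ± 0.21 (n = 2 samples) and NR4A2 1.94 ± 0.33. UAP1, an enzyme of UDP-sugar synthesis, had 2.15 ± 0.31 on 1 clone and 1.03 ± 0.23 on the other, which did not pass (adjusted p = 0.115). GINM1 (1.5 ± 0.16), the kinase CAMK2D (1.48 ± 0.24), NUCB2 (1.39 ± 0.20, n = 2 samples) and the fatty acid binding protein FABP3 (0.89 ± 0.14) were also positive. GMFB (-1.84 ± 0.23, n = 2 samples) and the RNA-binding protein RBM10 (-1.76 ± 0.26) were negative. Of 4 immediate early transcription factors 1 passed, and of 3 early response genes 2 passed, CCN2 (1.52 ± 0.28) and MCL1 (1.95 ± 0.38), on 1 value per gene. In the test of all clones neither passed (limma adjusted p = 0.0553 for CCN2 and 0.0760 for MCL1). Both lists had a camera adjusted p of 0.00956, but adjusted p = 0.0886 and adjusted p = 0.181 with an estimated correlation. By fry their adjusted p was 0.000813 and 0.000404. Fry also passed quiescence genes (adjusted p = 0.00083, 5 complete genes) and heat shock genes (adjusted p = 0.0229, 3 complete genes), so it did not single out the early lists. In each RAP target the estimated correlation and fry rest, for the immediate early and early response lists, on the same 3 complete genes as in RNA. Without slide 3, slide 4 or slides 1 and 2 of every target 0 clones passed in limma, with 237, 230 and 242 at an unadjusted p under 0.05. In a fit of primer28 alone and with slides 3 and 4 averaged as 1 sample 0 passed too, with 187 and 274 such clones. In the 16 lists without a passing member, 11 of 63 genes had an unadjusted p under 0.05, against 208 of all 1675 genes.

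Over all clones measured in both, r with RNA was 0.173 in primer19 (rho 0.139, 3698 clones), 0.253 in primer22 (rho 0.194, 3520 clones) and 0.121 in primer28 (rho 0.095, 3149 clones). Over the clones chosen for passing in RNA, which have a wider range of values, it was 0.496, 0.660 and 0.564. There, 78 of 101 clones had the sign of RNA in primer19, 83 of 97 in primer22 and 70 of 91 in primer28. Among positive calls, primer22 shared 22 of its 43 with RNA, where 0.721 were expected for independent calls (one-sided Fisher's exact test, BH-adjusted p = 5.19e-29). These included NR4A2, ZC3H12A, RGS16, IL11, CCN2, JUND, INSIG1, SLC2A3, SLN and PDE4D. Primer19 shared 6 of 13, with CCN2, ID4 and PRAME among them (0.214 expected, exact BH-adjusted p = 7.39e-08), and primer28 shared 3 of 11, with NR4A2 and UAP1 among them (0.192 expected, exact BH-adjusted p = 0.00151). The calls are not independent, since the fit gives a clone 1 spread for all targets, so a small spread favours passing in both. With no dye swap recorded, a dye effect of a clone may also be common to RNA and RAP. The expected numbers allow for neither. Of the negative calls 1 was shared in primer19 and 0 in primer22 and primer28. With 0.108, 0.151 and 0.0229 expected, these counts are too small to tell whether negative calls were shared. Among the top 200 clones by p, primer19 shared 13 negative clones with RNA (2.37 expected, exact BH-adjusted p = 5.998e-07). Primer22 shared 4 (2.38 expected, exact BH-adjusted p = 0.256) and primer28 shared 0 (2.498 expected). The same limits hold for these expected numbers. With slides 3 and 4 averaged as 1 sample, 1, 4 and 0 clones were shared with primer19, primer22 and primer28, both signs together, against 7, 22 and 3 as reported. Without slide 3 of every target these were 0, 3 and 0, without slide 4 0 in each, and without slides 1 and 2 0, 8 and 0, within ranges of 0 to 12, 0 to 27 and 0 to 4 over the slides left out. Fitted alone, 0 RAP clones passed in limma, so 0 were shared, and with quantile normalization 0 were shared with primer19. Over the clones with values on all 16 slides, r with RNA was 0.366, 0.545 and 0.305.

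**Figure D3:**
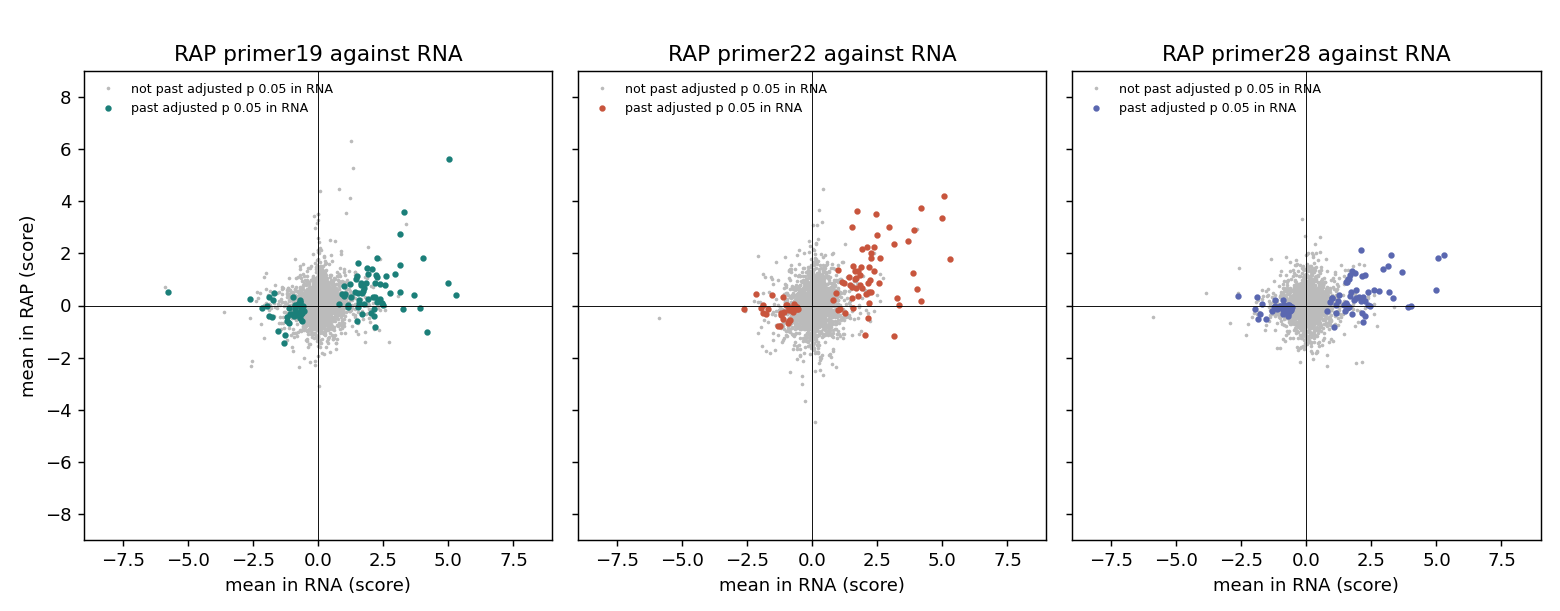
Mean value per clone in each RAP target (y axis, score) against RNA (x axis, score), 1 panel per primer; coloured points passed in RNA and grey points did not. Of the coloured points, 83 of 97 have the sign of RNA in primer22.

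Between primer means r was 0.151 for primer19 and primer22, 0.0047 for primer19 and primer28 and 0.045 for primer22 and primer28. CCN2 and NR4A2 were the named genes among the 5 clones that passed with a positive value in 3 targets, and 0 clones passed in all 4. The CCN2 clone fell short in primer28 (limma adjusted p = 0.0553), and on 1 value per gene CCN2 passed in all 4 targets. GINM1 and GMFB passed in 2 primers with opposite signs.

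Tested directly, RAP and RNA differed at 11 of 3698 clones for primer19 (1 positive and 10 negative), 13 of 3520 for primer22 (5 and 8) and 10 of 3149 for primer28 (3 and 7). NR4A2 was lower than in RNA by the deposited sign in every primer, by -4.89 ± 0.47 in primer19 (limma adjusted p = 0.00210), -3.52 ± 0.47 in primer22 and -3.36 ± 0.47 in primer28. ZC3H12A differed by -4.15 ± 0.38 in primer19 and -4.39 ± 0.38 in primer28, IL11 by -4.0 ± 0.49 and -3.97 ± 0.49, and MCL1 by -3.38 ± 0.54 in primer19. The TPM1 clone that passed in RNA differed by -2.54 ± 0.37, -2.62 ± 0.37 and -2.42 ± 0.37 in primer19, primer22 and primer28. In primer22 PRAME (-4.32 ± 0.60), CCL7 (-3.18 ± 0.44, n = 2 RAP samples) and TRIM24 (-1.61 ± 0.26) were lower than in RNA, and HS2ST1 (4.06 ± 0.33) and SNX10 (3.45 ± 0.52), each with n = 2 RAP samples, and MAMDC2 (1.31 ± 0.22) were higher. In primer28 GMFB was lower by -2.21 ± 0.30 and GINM1 higher by 1.34 ± 0.23. The 3 contrasts use the same RNA slides, so a chance value in RNA enters each of them. Each deposited array had been brought to 1 median absolute value by a factor that is unknown. Scores of RNA and RAP may therefore not share 1 unit, and a difference in size between values of 1 sign may come from this. NR4A2, at 1.78 in primer22 and 1.94 in primer28 against 5.30 in RNA, is such a case. Without slide 3 or slide 4 of every target 0 clones passed in any of the 3 contrasts with limma, where 200 to 228 had an unadjusted p under 0.05. Averaging slides 3 and 4 as 1 sample also left 0, with 238 to 271 at an unadjusted p under 0.05, and contrasts fitted alone gave 3, 12 and 1.

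On 1 value per gene, 12 lists of other functions and cell types had no passing member in RNA over all genes. They held 65 measured genes, of which 7 had an unadjusted p under 0.05 in limma, against 223 of all 2077 genes. Their lowest camera adjusted p was 0.225. TPM1, of the actin cytoskeleton list, had a mean of 0.94 ± 0.22 over its clones and passed adjusted over the list alone (adjusted p = 0.00683), as did DUSP8 (0.75 ± 0.23, adjusted p = 0.0247) among the feedback regulators. By fry, on 3 complete genes each, the actin cytoskeleton and heat shock lists had an adjusted p of 0.031. Median values in RNA were 0.28 for actin cytoskeleton genes, 0.11 for wound healing and matrix remodelling genes, 0.01 for quiescence genes, 0.07 for cell cycle genes, -0.07 for feedback regulators of signalling, 0.38 for heat shock and stress genes, 0.34 for interferon response genes, -0.05 for ribosomal proteins and 0.13 for housekeeping genes. Fibroblast and collagen matrix genes had a median of -0.11, epithelial and keratinocyte markers 0.01 and blood cell markers -0.07. The 2 endothelial markers on the array lacked values in enough RNA samples and had a median of -0.04 in primer19. One of them, VWF, was measured in the other primers, with -1.62 ± 0.48 in primer22 (limma adjusted p = 0.160, and 0.0107 adjusted over the list alone, in which it was the only member) and 0.15 ± 0.39 in primer28.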

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

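The tests of the early response genes and of whether RAP primer19 slide 4 holds another target were chosen after the results were seen, as was the test of a smaller spread among the clones present on all slides.

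RAP primer19 slide 4 stood apart from the other primer19 slides. It had 0 missing spots, and SST (10.3), ID4 (9.02), UPP1 (5.81) and MLX (-1.66) were farther from 0 on it than on the other slides. These genes were named for primer19 means that include slide 4. One explanation, set in advance, was that dim spots were not removed, or background not subtracted, on slide 4. Its bound was that values at spots missing on the other primer19 slides are no larger than elsewhere, a ratio of at most 1. The ratio of median absolute values was 1.15, below the 2.13 to 4.42 of the other 15 slides but above that bound. On those 15 slides such spots had the larger values, so kept dim spots alone need not give a low ratio. The bound thus bears on unsubtracted background, and the explanation stays open. Slide 4 also had the lowest SD of the 16 slides (0.89). Another target on the slide is argued against by its correlations, of which the lowest with primer19 (0.196) exceeded the highest with other targets (0.159) by 0.0364. No biological explanation was tested.

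Positive values of the early response genes in RNA may reflect a ratio of 60 min over 0 min. Of 12 members of the lists of immediate early transcription factors and early response genes, 83.3% had a positive RNA mean, against 56.8% of all 2077 genes, which does not pass (one-sided exact binomial test against that share, p = 0.0542). A dye bias acting on single clones whatever their function is argued against, since the members' median of 2.22 lay at percentile 100 of 10000 random gene sets, while a bias tied to brightness was not tested. The random sets reuse the values behind the camera tests of these 2 lists, already known by then, and add no separate evidence. The direction stays open, as the labels name no dye and the test was chosen once the values had been seen.

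Among the 1433 clones with values on all 16 slides, 210 RNA calls were negative and 47 positive. A constant shift of these clones could give this, and was tested by centring each array on them: negative calls were still 2.88 times the positive calls (164 against 57), over the bound of 1.5 set in advance. This argues against such a shift as the whole cause, while a trend with brightness within these clones was not tested, for lack of intensities. A smaller spread stays open too: the negative share was 44.0 percentage points above the 37.7% over all clones, but 63 of 66 positive and only 18 of 40 negative RNA calls over all clones had a size of 1 or more, so more small calls need not raise both signs alike. No biological explanation was tested.

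Of 70 groups of 4 slides tested for a slide far from the others, 6 held one, and 5 of the 6 were primer19 slide 4. A rate of 5% would give about 3.5. The groups include named genes chosen from these same values, so that rate need not hold. Apart from the missing spots, the cases on primer19 slide 4 were SST, ID4, UPP1 and MLX, named for means that include this slide. The remaining case was RNA slide 3, where the spots of a clone had a rank correlation of 0.395, the highest of the RNA slides.

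Several genes differed between RAP and RNA by the test of the difference itself. In primer19 minus RNA these were NR4A2 (-4.89), ZC3H12A (-4.15), IL11 (-4.0), MCL1 (-3.38) and TPM1 (-2.54). In primer22 minus RNA they were HS2ST1 (4.06), SNX10 (3.45), MAMDC2 (1.31), TRIM24 (-1.61), TPM1 (-2.62), CCL7 (-3.18), NR4A2 (-3.52) and PRAME (-4.32). In primer28 minus RNA they were GINM1 (1.34), GMFB (-2.21), TPM1 (-2.42), NR4A2 (-3.36), IL11 (-3.97) and ZC3H12A (-4.39). TPM1 stands here for the clone that passed in RNA. Its other clone had -0.26 in RNA, -0.11 in primer19 and 0.32 in primer22. Without slide 3 or slide 4 of every target 0 clones passed in these contrasts with limma, and the unknown scaling of the arrays may enter the sizes.

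Turning the sign of single samples gives 4 arrangements per target, too few for a share under 0.05. In each target 1 of the 4, the real one, gave as many clones. RNA had 106 clones against at most 3 in the others, primer19 had 23 against 0, primer22 had 58 against 5 and primer28 had 13 against 1. The 3 RAP and 3 RNA samples of a contrast make 10 splits, also too few for a share under 0.05. The real split, 1 of the 10, gave 11 clones in primer19 minus RNA, 13 in primer22 minus RNA and 10 in primer28 minus RNA, against at most 0, 0 and 1 in the others.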

How the results depend on the processing

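The alternatives on the spots of a clone, on RAP primer19 slide 4 alone and on centring over clones present on all slides were chosen after seeing the data. Counts below are clones past the threshold in limma, listed for RNA, primer19, primer22 and primer28, then for primer19, primer22 and primer28 minus RNA, and shared clones are those passing in RNA and a primer with 1 sign. Unless a value or the construction shows it, the cause was not tested. Values not named stayed within 1.5 times the reported count or within 1 SD between samples of the reported correlation. Scaling each array to 1 median absolute deviation changed no count, as the deposited arrays already share that scale, and robust eBayes and a least size of 1 moved no count by over 1.5 times. Quantile normalization gave 0 clones in primer19, 7 in primer19 minus RNA and 0 shared with primer19. Over clones with values on all 16 slides the counts were 257, 98 and 41 in RNA, primer19 and primer28, and 53 and 20 in primer19 and primer28 minus RNA. There the correlations with RNA were 0.366, 0.545 and 0.305, shared clones 32 with primer19 and 10 with primer28, lists passing in RNA 2, and the spread of primer22 0.147. Centred on those clones, RNA had 221, of which 74.2% were negative against 37.7% as reported. Clones with 1 sample gave 8 in primer19 and 22 in primer22 minus RNA, correlations of 0.0999, 0.122 and 0.0722, and 1 clone shared with primer19. Averaging slides 3 and 4, which leaves 2 samples, gave 20, 1, 15 and 0, then 0 in each contrast, with 1, 4 and 0 shared, a correlation of 0.285 for primer22, and 0 lists in primer28. Keeping all slides with a random block gave 206, 78 and 37 in RNA, primer19 and primer28, then 40, 28 and 18, with 23 shared with primer19 and 8 with primer28. The replicate block gave 69, 0 and 7 in RNA, primer19 and primer28, then 3, 3 and 6, with 0 shared with primer19 and 1 with primer28; IER3 turned to 0.22 in RNA and -0.27 in primer19. Between targets, 1 of 18 correlations between the deviations of equal sample numbers was over 0.1 (range -0.023 to 0.121). These values cannot settle whether the sample numbers pair the targets. Even technical duplicates in RNA correlated at only 0.227, below RNA slides 1 and 3 of different samples (0.329). Each target or contrast alone gave 17, 0, 0 and 0, then 3 in primer19 minus RNA and 1 in primer28 minus RNA, with 0 shared in each primer. With 1 value per gene, which tests fewer features, 37 passed in RNA and 7 in primer19 minus RNA, 3, 12 and 5 were shared, and primer28 correlated at 0.147. With 1 spot enough, 7 passed in primer19, 6 in primer28 and 5 in primer22 minus RNA, correlations were 0.121, 0.101 and 0.0686, 1 was shared with primer19, 1 list passed in primer28, and IER3 turned to 0.79 in RNA and -1.02 in primer19. With all 3 spots needed, 224, 94 and 24 passed in RNA, primer19 and primer28 and 17 in primer19 minus RNA, correlations were 0.296, 0.401 and 0.215, 25 were shared with primer19 and 9 with primer28, 1 list passed in primer22, and its spread was 0.196. The median of spots gave 8 in primer28, 4 shared with primer19 and 0 lists in primer28. Every spot as a feature gave 0, 94 and 2 in the 3 primers, then 6, 0 and 4, with correlations of 0.106, 0.104 and 0.0668. The top 200 clones by p shared 38, 40 and 17, of which 13, 4 and 0 were negative. Fry passed 2, 5 and 4 lists in the 3 primers, and camera with an estimated correlation 0 in primer22 and 0 in primer28. Where a count was 0, between 187 and 482 clones, or 837 and 1063 single spots, had an unadjusted p under 0.05. Leaving out slides (1 to 4 in turn in every target, slides 1 and 2 together, or primer19 slide 4) gave 12 to 105 in RNA, 0 to 51 in primer19, 1 to 61 in primer22 and 0 to 12 in primer28, then 0 to 15, 0 to 9 and 0 to 13. Shared clones ranged over 0 to 12, 0 to 27 and 0 to 4, correlations over 0.165 to 0.219, 0.223 to 0.282 and 0.0960 to 0.142, and passing lists over 1 to 4 in primer22 and 0 to 3 in primer28. Counts without slide 3 or slide 4 rest on 2 samples per target. All correlations with RNA stayed above 0. Of 1670 values of named genes under alternatives tested on clones, 4 turned sign, all of IER3, and 543 kept their sign but no longer passed. Among these were 74 when fitted alone, 71 with slides 3 and 4 averaged, 71 without slide 3 and 70 without slide 4. Of the 89 named values 87 had passed as reported, and some of the 87 lacked a value without slide 3 or slide 4. Named genes were not recomputed for 1 value per gene or single spots, and 45 of the 89 had a value among clones on all 16 slides. A filter on dim spots was not run, turning the sign only mirrors the values, and lists were not recomputed for fits of each target alone or for single spots.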

Other observations

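The genes of this part were chosen after their values were seen. Some early response genes outside the calls had large values in RNA. GEM, a GTPase, had 4.01 ± 0.72 and FOSL2, an AP-1 subunit, 2.71 ± 0.65 on 1 value per gene, with limma adjusted p of 0.0777 and 0.0831 over all genes and 0.00252 and 0.00319 adjusted over the list alone.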
